A study of Mus musculus with 6 samples.

How the data were processed

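Single-cell RNA sequencing was done on CD8 T cells sorted from MB49 tumours grown under the skin of C57BL/6 mice. MB49 is a mouse urothelial carcinoma cell line. Per the labels, mice aged 6 weeks were inoculated, tumours were taken on day 10, live cells positive for CD3 and CD8 and negative for CD4 were sorted, and libraries were made with a 10x Genomics 3' kit. The labels list 3 female and 3 male biological replicates and give no batch, date or litter.

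The submitters' processing notes name Cell Ranger, Seurat and the mouse genome build mm10, with no versions. The deposited table holds raw counts (unique molecular identifiers, UMIs) for 15601 genes and 26698 cells from all libraries. The deposited metadata gives, in other units, the sex of the host in words, the number of genes detected per cell and the authors' cluster number per cell. Its UMI total per cell is a count, which equalled the column sum of the deposited table in every cell, as did the number of genes above 0. The header ties the 11 clusters to an integrated assay. The filters on cells and genes are not given in the sources used here, nor is the treatment of doublets, and no doublets were removed here. The deposited cells held 501 to 8265 genes and 640 to 129226 UMIs each, and 423 genes had no count in any cell.

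The number after each barcode was taken as the library. Numbers 1, 3 and 4 held male cells alone and 2, 5 and 6 female cells alone, which gives 3 libraries per sex, each taken as 1 replicate. Which numbered replicate of the labels each library is could not be told. In all, 85 barcodes occurred under more than 1 library number. Gene positions came from GENCODE M21, which uses the same build, by symbol, and 11802 of the 12194 genes tested over all CD8 T cells had a match.

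Clusters were named from marker lists, by their members among the top 10 genes of a cluster and their level against the other clusters. Clusters 0 and 8 were named terminally exhausted-like, 1 effector-like, 3 and 5 proliferating-like, 7 naive or central memory-like and 9 interferon-stimulated-like. Cluster 2 had 4 markers of natural killer or innate-like cells among its top 10 and was named innate-like. Clusters 4, 6 and 10 stayed unnamed. Clusters 6 and 10 had medians of 1742 and 1461 UMIs per cell and median mitochondrial shares of 30.03% and 20.28%. No cluster could be named progenitor exhausted-like, so the planned test of the sex effect between that class and the terminally exhausted-like class was not run. Cluster 7 was set against clusters 0 and 8 in its place, a choice made after the data were seen.

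Counts were summed per library over all cells outside cluster 2, and per library and cluster, with at least 20 cells per sum. The smallest sum held 93 cells. Sums were compared with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with robust dispersion, after edgeR's filter on low counts and TMM normalization. P-values were adjusted by the Benjamini-Hochberg method, over genes within each comparison, and a gene was called at an adjusted p under 0.05. Log2 fold changes are coded male minus female. Levels are CPM of the sums as computed by edgeR, given as mean ± SD over 3 libraries per sex. The model for the added comparison held the library as a block and the cluster group by sex interaction.

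Cluster shares were compared with edgeR on cell counts, with the total cells of the library as library size, adjusted over the 11 clusters. Beside it stands an exact two-sided permutation test of the difference of mean shares, with 20 assignments of the 6 libraries and a smallest possible p of 0.10. Shares of single libraries have exact binomial intervals at 95%, computed in R. Intervals and floors cover counting error alone. Where a sex had no UMI of a gene, the fold is a lower bound against a floor of 3 counts over the summed libraries of that sex.

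In all, 30 gene lists were fixed before the data were examined, and so were the comparisons, the markers, the rule for named genes and the alternatives not said to be added. Of these lists, 26 had at least 3 members tested over all CD8 T cells. Lists were tested with camera in limma 3.58.1 on log CPM with a prior count of 3 and a preset inter-gene correlation of 0.01, adjusted over lists, or over all 270 list and cluster tests. The same test with an estimated correlation, and fry, which asks whether the genes of a list move one way on balance, were run beside it.

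Named genes followed a rule. It takes the measured Y-linked genes with Xist, Kdm6a, Kdm5c, Ddx3x and Eif2s3x. It takes up to 12 called genes per direction outside the 2 label-check lists (Y-linked genes, and Xist with X-inactivation escape genes) and outside gene models, with a mean of at least 5 CPM and no overlap between the sexes. Where fewer were called, up to 5 more per direction by unadjusted p are named as not passing. It takes up to 4 members of each list with the smallest p, 3 genes per direction within each cluster, and 5 genes of the interaction. A few results that this rule would name are not reported here. Other genes named were chosen after their values were seen, and the text says so.

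Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, library size alone, no filter beyond 1 count, a filter at 10 CPM in 3 libraries, counts thinned to the smallest total, the 16757 cells with at least 1000 UMIs and under 5% mitochondrial UMIs, all deposited cells, a minimum of 50 cells per sum, and each library left out in turn. Shares were also tested by quasi-binomial regression, with TMM over clusters, and on Leiden clusters. These were recomputed with leidenalg 0.10.2 from 2000 variable genes, 30 principal components and 20 neighbours at a resolution of 0.5, without the label-check genes. Chosen after seeing the data were sums without clusters 6 and 10, sums with the same cluster mix in every library, the interaction test and its alternatives. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 prepared and plotted the data.

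The tests were tested on simulated data with 200 changed genes in each of 8 draws. For the sums over all CD8 T cells, edgeR recovered 43.2%, 87.3% and 99.4% of genes changed by a log2 of 0.5, 1 and 2, with 9.2% false calls, against 49.8%, 88.7% and 98.2% for DESeq2, with 14.6% false calls, while limma-voom had 9.3% false calls. In cluster 1 the recovery was 29.1%, 87.9% and 99.8%, with 6.3% false calls, against 20.4%, 78.1% and 99.2% for DESeq2, with 3.2% false calls. In the interaction it was 22.7%, 69.9% and 93.8%, with 7.6% false calls. The interaction draws gave each unchanged gene the same level in both cluster groups. Their rates therefore do not cover genes that are low in 1 group and high in the other. With no gene changed, 4.74% to 5.22% of unadjusted p-values were under 0.05, and 0 to 4 genes were called per draw. A doubled share of cluster 7 was recovered in 15 of 20 draws, with 3 calls of other clusters over all draws. The spread between libraries was preset in these draws and smaller than that of cluster 7 in the data. The recovery therefore holds for that smaller spread alone.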

Results

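The data describe CD8 T cells from MB49 tumours of female and male mice, with 3 biological replicates per sex, and the labels set the sexes against each other. The deposited cells numbered 9955 from females and 16743 from males, with 295211042 UMIs in total. Female library 2 held 2892 cells and 40775907 UMIs, female library 5 held 4942 cells and 61434194 UMIs, and female library 6 held 2121 cells and 25562319 UMIs. Male library 1 held 6305 cells and 59753027 UMIs, male library 3 held 3282 cells and 41580277 UMIs, and male library 4 held 7156 cells and 66105318 UMIs. The median number of UMIs per cell was 9517.7 ± 546.1 in females and 7527.8 ± 1485.2 in males (mean and SD of the library medians, n = 3 each). With the innate-like cluster 2 left out, the sums that were compared held 23820769 to 62292575 UMIs.

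The first comparison asked how gene expression over all CD8 T cells differed between the sexes. Genes on the sex chromosomes separated the libraries by sex. Ddx3y, a Y-linked RNA helicase gene, had 12305 UMIs in males and 0 in females, at least 3331-fold higher. Uty and Kdm5d, Y-linked histone demethylase genes, had 2804 and 2815 UMIs in males and 0 in females, at least 759-fold and 762-fold higher. Eif2s3y, which encodes a translation initiation factor subunit, had 14353 UMIs in males and 3 in females. Xist, the RNA that silences 1 X chromosome in female cells, had 90206 UMIs in females and 4 in males. Of the genes known to escape that silencing, Kdm6a (chromosome X, 18162575 to 18279936) stood at 47.8 ± 2.68 CPM in females and 25.7 ± 1.63 CPM in males (n = 3 each, log2 fold change -0.89, SE 0.083, adjusted p = 0.00221). Eif2s3x was lower in males by a log2 fold change of -0.76 (adjusted p = 0.00677) and Kdm5c by -0.68 (adjusted p = 0.0273). The call of Kdm5c was lost in 6 of 17 alternatives, with an adjusted p of up to 0.135. Ddx3x was not called, at 131 ± 26.2 CPM in females and 119 ± 15.1 CPM in males, and its log2 fold change of -0.14 became 0.03 without female library 6. Apart from Ddx3x, whose levels overlapped between the sexes, no library stood on the side of the other sex for these markers.

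Outside these label-check genes, Gzma, which encodes the cytotoxic granule protease granzyme A, was 2.32-fold higher in females. Its level was 1702 ± 204 CPM in females and 733 ± 94.3 CPM in males (n = 3 each, log2 fold change -1.21, SE 0.127, adjusted p = 0.00531), and each female library stood above each male library. Gzma lies on chromosome 13 from 113093825 to 113100981 and was covered by 201661 UMIs in females and 110009 in males. Its call held in 17 of 17 alternatives, at log2 fold changes of -1.32 to -1.12 and a highest adjusted p of 0.0437. Tsix, annotated antisense to Xist, stood at 11.8 ± 1.40 CPM in females and 0.313 ± 0.0237 CPM in males (log2 fold change -5.24). Tsix overlaps Xist, and the strand used in counting is not stated. Gm29650, a non-coding gene model on chromosome Y named after its values were seen, had 98 UMIs in males and 0 in females, at least 26.5-fold higher.

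**Figure D1:**
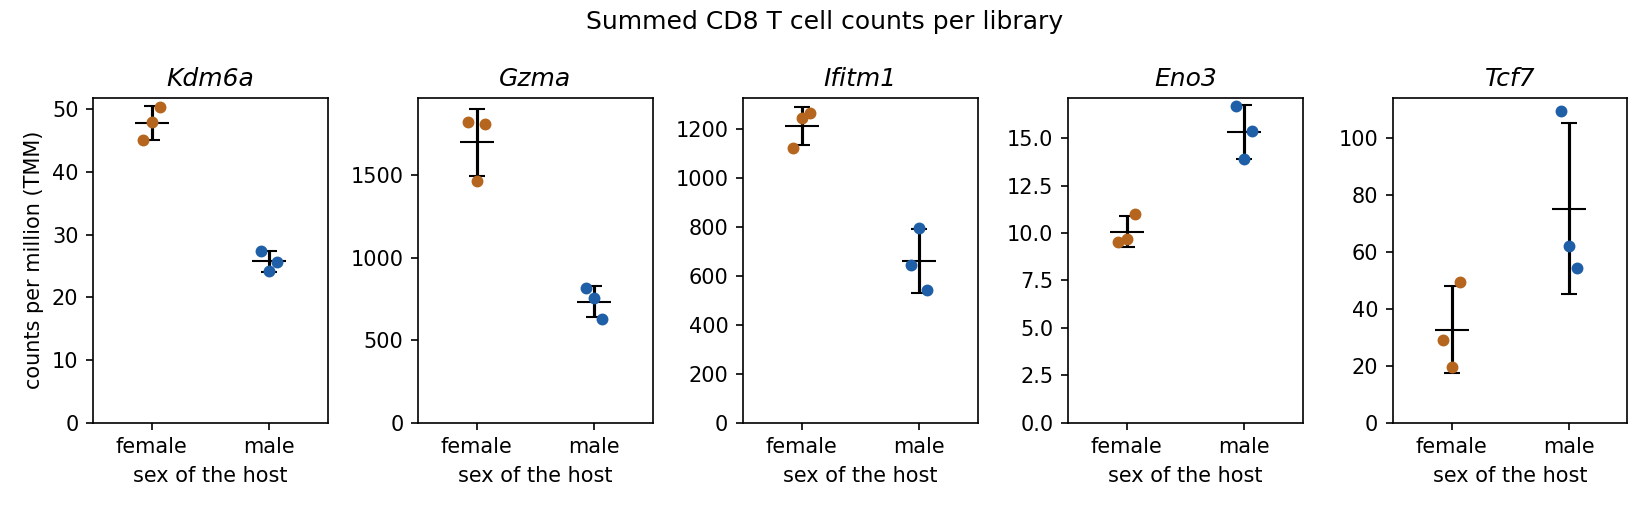
Level in CPM of Kdm6a, Gzma, Ifitm1, Eno3 and Tcf7 in each of the 6 libraries, with points for libraries and bars for the mean ± SD of 3 libraries per sex. Kdm6a and Gzma passed the test between the sexes, with Gzma at a mean of 1702 CPM in females and 733 CPM in males, while Ifitm1, Eno3 and Tcf7 did not.

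The next genes on the ranking did not pass the test. Ifitm1, an interferon-inducible membrane protein gene, stood at 1212 ± 76.8 CPM in females and 661 ± 129 CPM in males (log2 fold change -0.88, adjusted p = 0.0852). It passed in 6 of 17 alternatives, whose adjusted p ranged from 3.55e-08 to 0.339. Ccl9, a chemokine gene, had a log2 fold change of -1.23, Ifitm2 of -0.96, Cd200r1 of -0.75 and the nuclear lamina gene Lmna of -0.67. On the male side, the muscle-type enolase gene Eno3 stood at 10.1 ± 0.817 CPM in females and 15.3 ± 1.41 CPM in males (log2 fold change 0.61, adjusted p = 0.114). Axin2, a target and inhibitor of Wnt signalling, had a log2 fold change of 0.75, Zcchc18 of 0.77, Frat2 of 0.61 and Mylip of 0.58. Named after its values were seen, Tcf7, a transcription factor gene of the stem-like list, stood at 32.6 ± 15.3 CPM in females and 75.1 ± 29.9 CPM in males (log2 fold change 1.22, adjusted p = 0.555). By cluster, Tcf7 was highest in the innate-like cluster 2 (342 CPM) and the naive or central memory-like cluster 7 (333 CPM). Cluster 2 is left out of these sums, and no cluster could be named progenitor exhausted-like. Pdcd1, which encodes the inhibitory receptor PD-1 and was chosen in the same way, was not called either, at 365 ± 92.5 and 361 ± 50.5 CPM.

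In all, 12194 genes were tested with edgeR and 11 were called, 5 higher in males and 6 higher in females, of which 3 lay outside the label-check lists. At an unadjusted p under 0.05 there were 1020 genes, 653 higher in males and 367 higher in females. DESeq2 called 136 genes, 95 of them higher in males, and 127 outside the label-check lists, 91 higher in males and 36 higher in females, while limma-voom called 11. The count outside the label-check lists ran from 2 to 9 when 1 library was left out: 9 without male library 4, 6 without male library 3, 5 without female library 6, and 2 without male library 1 or without female library 5.

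Gene lists of T cell states differed in direction between the sexes. Of 15 stem-like and progenitor exhausted T cell genes, 14 were higher in males (camera adjusted p = 2.15e-05; adjusted p = 0.380 with an estimated correlation), none was called over all genes and 4 were called adjusted over the list alone. Among them, Id3 stood at 4.14 ± 1.37 CPM in females and 11.3 ± 3.58 CPM in males, and Tnfsf8, which encodes CD30 ligand, at 11 ± 3.45 and 27.5 ± 8.54 CPM. Both were among the top genes of the naive or central memory-like cluster 7, whose mean share was larger in males. Bach2 and Bcl6, transcriptional repressor genes, had log2 fold changes of 0.60 and 0.50. Of 12 naive and central memory T cell genes, 10 were higher in males (adjusted p = 1.52e-05; adjusted p = 0.380 with an estimated correlation), and 6 were called adjusted over the list alone. Ccr7, the lymph node homing receptor gene, stood at 38.4 ± 10.3 CPM in females and 81.9 ± 27.5 CPM in males, with log2 fold changes of 1.05 for Klf3, 1.11 for Nsg2 and 0.44 for Lef1.

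The opposite direction was seen for exhaustion genes, 15 of 18 of which were lower in males (adjusted p = 0.000168; adjusted p = 0.397 with an estimated correlation), with 0 called adjusted over the list alone. Cxcr6, a chemokine receptor gene of tissue T cells, had a log2 fold change of -0.47, Id2 of -0.45, the ectonucleotidase gene Entpd1 of -0.40 and Cd38 of -0.25. Of 20 effector and cytotoxicity genes, 17 were lower in males (adjusted p = 0.000593; adjusted p = 0.380 with an estimated correlation), and Gzma alone was called, over all genes and adjusted over the list alone. Gzmk, Klrg1 and Gzmb had log2 fold changes of -0.43, -0.45 and -0.54. Of 29 proliferation genes, 28 were lower in males (adjusted p = 2.56e-10; adjusted p = 0.380 with an estimated correlation), with Kif20a at -0.33, Kif11 at -0.32, Tpx2 at -0.27, Bub1 at -0.26, and 0 called adjusted over the list alone. Of 21 T cell receptor signalling response genes, 15 were lower in males (adjusted p = 0.0481; adjusted p = 0.604 with an estimated correlation), with Il2ra at -0.45, Ier3 at -0.44 and Tnfrsf9 at -0.37 against Nr4a2 at 0.23, and 0 called adjusted over the list alone.

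Interferon-stimulated genes were higher in males for 28 of 31 members (adjusted p = 2.21e-09; adjusted p = 0.380 with an estimated correlation), and 10 were called adjusted over the list alone. Iigp1, an interferon-induced GTPase gene, stood at 2.12 ± 0.681 CPM in females and 6.50 ± 1.62 CPM in males, and Ifit3b, Gbp2 and Ifi47 had log2 fold changes of 1.39, 0.48 and 0.37. Of 13 transforming growth factor beta response genes, 10 were higher in males (adjusted p = 0.0432; adjusted p = 0.380 with an estimated correlation; fry adjusted p = 0.0480), and 2 were called adjusted over the list alone. Smad7, an inhibitor of that pathway, had a log2 fold change of 0.27, Ldlrad4 of 0.46 and Tgif1 of 0.24.

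Metabolic lists were lower in males by small amounts. All 16 glycolysis genes tested were lower in males (adjusted p = 0.000394; adjusted p = 0.477 with an estimated correlation), at a median log2 fold change of -0.15, among them the glucose transporter genes Slc2a3 at -0.35 and Slc2a1 at -0.32, then Pfkl at -0.17 and Pgam1 at -0.15. Of 16 hypoxia genes, 15 were lower in males (adjusted p = 5.65e-05; adjusted p = 0.380 with an estimated correlation), with Bnip3 at -0.69, Egln3 at -0.56, Ero1l at -0.38, and 1 called adjusted over the list alone. Of 33 oxidative phosphorylation genes, 29 were lower in males (adjusted p = 0.000150; adjusted p = 0.477 with an estimated correlation), with Atp5k at -0.24, Cox7c at -0.20, Cox6b1 at -0.18 and Ndufc1 at -0.17. Ribosomal protein genes went the other way, with 32 of 34 higher in males (adjusted p = 3.04e-05; adjusted p = 0.477 with an estimated correlation), at a median of 0.12, with Rpl5 at 0.22, Rpl13 at 0.21, Rps6 at 0.17 and Rps20 at 0.17. None of the glycolysis, oxidative phosphorylation or ribosomal genes was called adjusted over the list alone. Beside these lists, the median UMIs per cell were 6976 and 6397.5 in male libraries 1 and 4 and 9043 to 10114.5 in the other 4 libraries.

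Markers of CD4 and regulatory T cells, which the sort should have removed, were lower in males for 6 of 6 members (adjusted p = 0.0432; adjusted p = 0.380 with an estimated correlation), with 0 called adjusted over the list alone, and 2 of the 6 are also on another list. Foxp3 stood at 2.31 ± 1.47 CPM in females and 0.557 ± 0.484 CPM in males, Ikzf4 at 27.2 ± 6.78 and 18.5 ± 3.84 CPM, and Ccr8 at 3.29 ± 1.96 and 1.76 ± 0.883 CPM. Cd4 itself was at most 1.0 CPM in any cluster, as a mean over libraries, so the list does not show that CD4 T cells were present. Cd40lg had a log2 fold change of -0.37, which became 0.32 without female library 2. The Y-linked list (4 of 4 higher in males and called; adjusted p = 6.70e-28; adjusted p = 0.0445 with an estimated correlation) and the list of Xist and X-inactivation escape genes (8 of 9 lower in males; adjusted p = 5.79e-09; adjusted p = 0.377 with an estimated correlation) followed the labels. Over the list alone, 4 and 5 members of these lists were called.

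The remaining lists were not called by camera. Higher in males were 7 of 14 X-linked immune genes (adjusted p = 0.786), 3 of 10 tissue residency genes (adjusted p = 0.206), 11 of 16 immediate early and dissociation genes (adjusted p = 0.111) and 11 of 13 heat shock genes (adjusted p = 0.158). So were 17 of 45 androgen-responsive genes (adjusted p = 0.158), 7 of 11 glucocorticoid-responsive genes (adjusted p = 0.111) and 9 of 13 mitochondrially encoded genes (adjusted p = 0.206). Adjusted over the list alone, 1 X-linked immune gene (Tlr7, a receptor for RNA, log2 fold change 1.83), 1 tissue residency gene (Rgs2, 0.48), 1 androgen-responsive gene (Zbtb10, 1.47) and 3 glucocorticoid-responsive genes (Klf9 at 0.43, Cebpb at 0.41 and Sgk1 at -0.32) were called. Among markers of other cell types, 4 of 14 myeloid markers (adjusted p = 0.193), 6 of 7 MHC class II genes (adjusted p = 0.0689), 3 of 10 natural killer and innate-like markers (adjusted p = 0.994) and 4 of 7 tumour epithelial markers (adjusted p = 0.629) were higher in males, with 0 called adjusted over the list alone. Cluster 2, named innate-like from such markers, is left out of these sums. The result for the natural killer list therefore does not cover the cells where these markers were highest. Too few members for a set test were measured of the B cell list (Cd79b, 0.15), the gamma-delta T cell list (Cd163l1, 1.20), the fibroblast and endothelial list (Pecam1, 0.44) and the red blood cell list (Hbb-bs, -0.94). Each of these lists had 1 member tested, so an adjustment over the list alone leaves the unadjusted edgeR p. That p was under 0.05 for Cd163l1 and not for the others, and none of them was called over all genes. The gamma-delta list as a whole summed to 1.35 CPM in females and 3.03 CPM in males.

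Of 26 lists tested, camera called 15. With an estimated correlation, 1 of these calls held, that of the Y-linked genes, and fry called 3, the label-check lists and the transforming growth factor beta response genes. With the same cluster mix in every library, an alternative chosen after seeing the data, the calls of the interferon-stimulated (adjusted p = 0.0816), proliferation (adjusted p = 0.294), T cell receptor signalling (adjusted p = 0.526) and transforming growth factor beta (adjusted p = 0.151) lists were lost. The median, mean and camera direction differed in sign for the X-linked immune, androgen-responsive and tumour epithelial lists, and camera's direction differed from both for the natural killer list.

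The shares of cells per cluster asked whether the mix of CD8 T cell states differed between the sexes. Cluster 7, the naive or central memory-like cells, made up 3.81% ± 1.10 of cells in females and 8.47% ± 2.72 in males (SD, n = 3 each), a log2 ratio of 1.17 (SE 0.292, edgeR adjusted p = 0.0169, exact permutation p = 0.10). The male libraries 1, 3 and 4 stood at 11.3%, 8.20% and 5.90%, and the female libraries 2, 5 and 6 at 4.36%, 2.55% and 4.53%, with the interval nearest between the sexes from 5.36% to 6.47% in male library 4 and from 3.68% to 5.50% in female library 6. The call was lost without male library 1 (log2 ratio 0.90, adjusted p = 0.0899) and without male library 3 (log2 ratio 1.19, adjusted p = 0.0676). It was lost too with quasi-binomial regression (adjusted p = 0.160), with filtered cells (edgeR adjusted p = 0.0894) and with Leiden clusters (edgeR adjusted p = 0.0674), so that it held in 5 of 10 alternatives.

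No other cluster's share passed the test. The innate-like cluster 2 made up 7.66% ± 3.50 in females and 14.98% ± 4.30 in males (edgeR adjusted p = 0.0671), and the interferon-stimulated-like cluster 9 made up 3.78% ± 0.594 and 5.57% ± 0.426 (edgeR adjusted p = 0.0730). The terminally exhausted-like cluster 0 made up 20.5% ± 4.34 in females and 16.4% ± 2.78 in males, and cluster 8 made up 7.89% ± 1.49 and 5.54% ± 1.77. The proliferating-like cluster 3 stood at 11.2% ± 0.371 and 8.13% ± 1.05, cluster 5 at 10.1% ± 0.538 and 7.81% ± 1.24, and the effector-like cluster 1 at 10.9% ± 0.993 and 14.4% ± 2.41. Cluster 4, whose top genes were Il2, Ccl4 and Ccl3, made up 10.6% ± 1.66 in females and 7.91% ± 1.90 in males, and the low-UMI clusters 6 and 10 made up 9.40% ± 1.82 and 4.35% ± 0.534 in females and 6.78% ± 1.33 and 4.08% ± 0.533 in males.

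**Figure D2:**
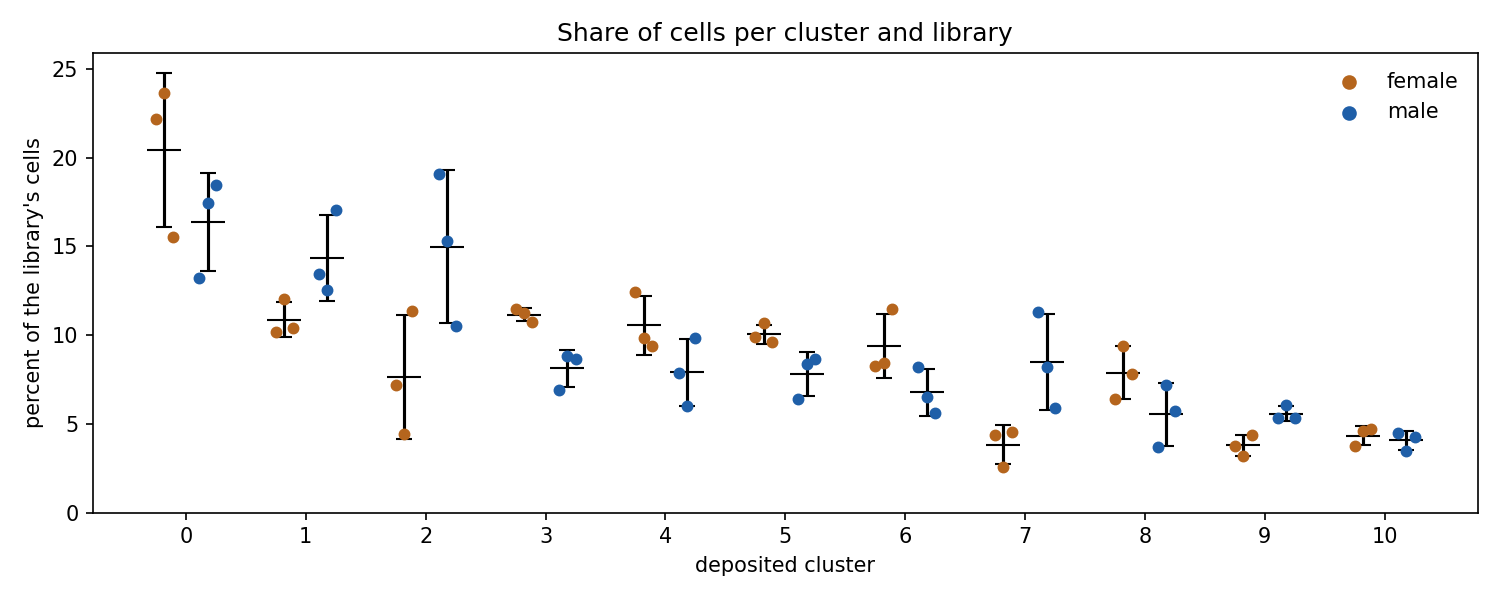
Share of cells in percent for each of the 11 clusters in each library, with points for libraries and bars for the mean ± SD of 3 libraries per sex. Cluster 7 stands at a mean of 3.81% in females and 8.47% in males and was the 1 share that passed the edgeR test, a call that held in 5 of 10 alternatives.

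The comparison within clusters asked whether the sexes differed within cells of 1 state. In the effector-like cluster 1, 343 genes outside the label-check lists were called, 144 higher in males and 199 higher in females. Treml2 stood at 2.89 ± 1.17 CPM in females and 16.1 ± 7.31 CPM in males (n = 3 each, log2 fold change 2.49, SE 0.477, adjusted p = 0.0201), and Irs2, an insulin receptor adaptor gene, at 5.21 ± 1.88 and 21.4 ± 7.14 CPM (log2 fold change 2.12, adjusted p = 0.00389). Fam101b had a log2 fold change of 1.88. Anxa1, which encodes annexin A1, stood at 50.3 ± 9.28 CPM in females and 16.7 ± 5.38 CPM in males (log2 fold change -1.68, adjusted p = 0.000145), and Cbfa2t3 had a log2 fold change of -1.62. The call of Treml2 was lost in 4 of 8 alternatives, with an adjusted p of up to 0.201. Of the fixed lists, 7 of 18 exhaustion genes were called lower in males in this cluster (11 adjusted over the list alone; camera adjusted p = 2.13e-09; adjusted p = 0.440 with an estimated correlation). Examples chosen after their values were seen are Cxcr6 at 660 ± 158 CPM in females and 295 ± 48.5 CPM in males, Id2 at a log2 fold change of -0.66 and Bhlhe40 at -0.56. Chosen in the same way, Lef1 and Klf3 of the naive and central memory list were called higher in males at 0.66 and 0.79, and Gzma was called lower at -1.15. The call of Klf3 was lost in 4 of 9 alternatives (adjusted p up to 0.0983), and those of Lef1 (up to 0.107), Cxcr6 (up to 0.0704) and Bhlhe40 (up to 0.0612) in 1 of 9. Of 34 ribosomal protein genes in cluster 1, 8 were called higher in males (25 adjusted over the list alone; camera adjusted p = 2.14e-09; adjusted p = 0.540 with an estimated correlation).

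In the interferon-stimulated-like cluster 9, 268 genes outside the label-check lists were called, 86 higher in males and 182 higher in females. Ifitm2 stood at 320 ± 50.5 CPM in females and 62.9 ± 21.8 CPM in males (n = 3 each, log2 fold change -2.34, SE 0.234, adjusted p = 0.000368), and its neighbour gene Ifitm3 at 230 ± 36.02 and 46.2 ± 21 CPM (log2 fold change -2.31, adjusted p = 0.0306). Higher in males were Arhgap5 at 4.76 ± 2.45 CPM in females and 21.4 ± 3.84 CPM in males (log2 fold change 2.30), with Rab20 at 1.76 and Zcchc18 at 1.73. The call of Rab20 was lost in 7 of 8 alternatives, with an adjusted p of up to 0.214, and those of Ifitm3 (up to 0.204) and of Iigp1, named below (up to 0.121), in 4 of 9. Of 19 effector and cytotoxicity genes, 6 were called lower in males (10 adjusted over the list alone; camera adjusted p = 1.64e-10; adjusted p = 0.439 with an estimated correlation), and 8 of 17 exhaustion genes were (13 adjusted over the list alone; camera adjusted p = 1.81e-11; adjusted p = 0.432 with an estimated correlation). Examples chosen after their values were seen are the perforin gene Prf1 at 194 ± 64.4 CPM in females and 73.6 ± 12.4 CPM in males, Ctla4 at a log2 fold change of -0.96 and Entpd1 at -1.27. Chosen in the same way, Il2ra, Nr4a3 and Irf4, induced by T cell receptor signalling, were called lower in males at -1.28, -0.98 and -0.86. By the same choice, the stem-like genes Id3 and Bach2 were called higher in males at 1.66 and 0.99, and so were Ccr7 at 1.46 and the interferon-stimulated genes Iigp1 at 1.53, Ifit3b at 0.89 and Ifit3 at 0.78. Lost in 2 of 9 alternatives were the calls of Ccr7 (adjusted p up to 0.154), Id3 (up to 0.0532), Ifit3 (up to 0.0774) and Irf4 (up to 0.0623), and in 1 of 9 those of Bach2 (up to 0.175) and Ifit3b (up to 0.0623). DESeq2 gave no adjusted p for Arhgap5 and Zcchc18, whose calls held in the other 8.

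**Figure D3:**
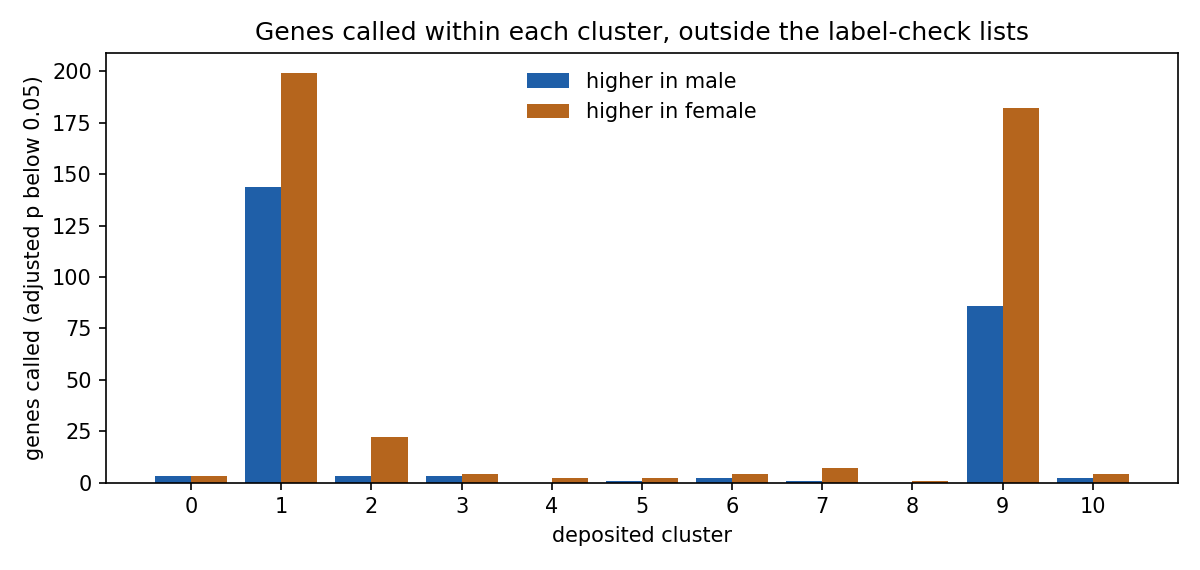
Number of genes called within each of the 11 clusters outside the label-check lists, in bars for genes higher in males and genes higher in females. Clusters 1 and 9 hold 343 and 268 calls, and the next cluster, 2, holds 25.

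Few genes were called in the other clusters. In the terminally exhausted-like cluster 0, 6 genes were called, among them Tnfsf8, higher in males at 6.64 ± 1.73 CPM in females and 15.5 ± 2.21 CPM in males (n = 3 each, log2 fold change 1.30, adjusted p = 0.0174), and Ifitm1, lower at 714 ± 95.6 and 330 ± 71.3 CPM (log2 fold change -1.11, adjusted p = 0.0129). Gzma was lower there at -0.95. In cluster 8, Tsix alone was called. Among proliferating-like cells, Tnfsf8 (1.41), Eno3 (0.86), Nr4a2 (0.47), Gzma (-1.25) and Egln3 (-0.87) were among 7 called genes of cluster 3, and Ifitm1 (-0.70) among 3 of cluster 5. The innate-like cluster 2 had 25 called genes, with Rgs10 (0.64), Acp5 (0.60) and Ly6c2 (0.48) higher in males and Anxa1 (-2.16) and AA467197 (-1.69) lower. In the naive or central memory-like cluster 7, 8 genes were called, with Zfp318 (0.99) higher in males and the sulfotransferase gene Chst2 (-1.78) lower. Named after its values were seen, the galectin gene Lgals1 was called lower there too (-0.78, edgeR adjusted p = 0.000662). That call was not followed over the alternatives. Cluster 4 had 2, Tsix and the heme oxygenase gene Hmox1 (-1.14). The low-UMI clusters had 6 each, with Tcf7 (2.00) and Cxcl10 (1.57) higher in males and Cd244 (-1.30) and Ifitm2 (-1.16) lower in cluster 6, and Ccr7 (1.72) and Tcf7 (1.44) higher and Uqcc2 (-1.40) and Adam8 (-1.32) lower in cluster 10. Several of these calls were lost in most alternatives. Zfp318 lost its call in 7 of 9 (adjusted p up to 0.210), Chst2 in 6 of 8 (up to 0.488), Uqcc2 in 7 of 9 (up to 0.449) and Cxcl10 in 6 of 9 (up to 0.994). Lost in 5 of 9 were the calls of Acp5 (up to 0.176), Egln3 (up to 0.326), Nr4a2 (up to 0.266), Hmox1 (up to 0.481) and Adam8 (up to 0.608). Lost in 4 of 9 were Ly6c2 (up to 0.457), Eno3 (up to 0.235), Ifitm1 in cluster 5 (up to 0.159) and Ccr7 in cluster 10 (up to 0.635), and in 3 of 9 Tnfsf8 in clusters 0 and 3 (up to 0.0839 and 0.0960), Ifitm1 in cluster 0 (up to 0.106) and Tcf7 in clusters 6 and 10 (up to 0.236 and 0.699). Lost in 2 of 9 were Gzma in cluster 0 (up to 0.129) and Cd244 (up to 0.0628), in 1 of 9 Rgs10 (up to 0.0676) and Ifitm2 in cluster 6 (up to 0.0504), and in 1 of 8 Anxa1 in cluster 2 (up to 0.0843).

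Over all clusters, 675 calls lay outside the label-check lists, 245 higher in males and 430 higher in females. The counts of clusters 1 and 9 moved with single libraries. Without female library 5 they were 56 and 65, without male library 1 they were 113 and 107, and without male library 3 they were 175 and 149. For cluster 1 the count was 195 without female library 2 and 702 without female library 6. A larger count in a cluster does not show that the sex effect differed between clusters, which was tested for cluster 7 against clusters 0 and 8 alone.

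List tests within clusters gave 117 calls among 270 tests. Naive and central memory genes were called higher in males in 10 of 11 clusters, all but cluster 7, and stem-like genes in 9, all but clusters 2 and 7. Exhaustion genes and glycolysis genes were called lower in males in 8 clusters each, effector genes and hypoxia genes in 7 each, and oxidative phosphorylation genes in 6. Ribosomal protein genes were called higher in 6 and interferon-stimulated genes in 5. T cell receptor signalling genes were called lower in clusters 1, 2, 4, 9 and 10, tissue residency genes lower in 10, and proliferation genes lower in 3 and higher in 4. Among markers of other cell types, MHC class II genes were called higher in males in cluster 3 (median log2 fold change 2.35, camera adjusted p = 3.85e-05; adjusted p = 0.440 with an estimated correlation). Natural killer and innate-like markers were called higher in clusters 0 and 4 and lower in 2, CD4 and regulatory T cell markers lower in 0 and 3, and myeloid markers lower in 2 and 3. Of the lists tied to stress and handling, heat shock genes were called higher in clusters 0, 1, 2 and 10, mitochondrially encoded genes in 2, 8 and 9, immediate early and dissociation genes in 0, 2, 5, 8 and 10, and glucocorticoid-responsive genes in 0. With an estimated correlation 12 calls held, those of the Y-linked list in 11 clusters and that of Xist and X-inactivation escape genes in cluster 8. For the other lists called, the lowest was an adjusted p = 0.173 with an estimated correlation, for effector genes in cluster 6.

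The added comparison asked whether the difference between the sexes was the same in cluster 7 as in the terminally exhausted-like clusters 0 and 8. In the exhausted-like cells, Tcf7 stood at 10.2 ± 3.91 CPM in females and 27.8 ± 11.1 CPM in males (SD, n = 3 each), against 355 and 312 CPM in cluster 7 (difference of log2 fold changes -1.59, SE 0.188, adjusted p = 0.00393). Tnfsf8 stood at 5.10 ± 1.135 and 12.5 ± 2.73 CPM in the exhausted-like cells and at 104 and 114 CPM in cluster 7 (difference -1.05, SE 0.180). Tmem108 stood at 0.137 ± 0.132 and 1.38 ± 0.584 CPM against 33.6 and 28.0 CPM (difference -3.06, SE 0.542), and Tdrp at 0.411 ± 0.208 and 1.98 ± 0.486 CPM against 32.5 and 27.0 CPM (difference -2.26, SE 0.405). The costimulatory receptor gene Tnfrsf4 stood at 24.1 CPM in females and 7.52 CPM in males in cluster 7 against 338 and 309 CPM in the exhausted-like cells (difference -1.45, SE 0.229, adjusted p = 0.00168). Its difference between the sexes within cluster 7 alone did not pass (log2 fold change -1.72, adjusted p = 0.242). Nor did those of Tcf7 (adjusted p = 0.784), Tnfsf8 (adjusted p = 0.0516) and Tdrp (adjusted p = 0.227) within the exhausted-like cells alone, where Tmem108 was too low to be tested. Of 10397 genes tested, 11 were called, all with a smaller male excess or a larger female excess in cluster 7, and 707 had an unadjusted p under 0.05. The count was 4 without male library 1 or without female library 5, 19 without male library 3 and 47 without female library 2. Without male library 1 the calls of Tnfsf8, Tmem108 and Tdrp were lost (adjusted p = 0.0605), without female library 2 that of Tcf7 (adjusted p = 0.0546), and without female library 5 that of Tmem108 (adjusted p = 0.0639).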

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

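The comparison of cluster 7 with clusters 0 and 8, its free RNA test and its count over other splits were chosen after the results were seen, while the doublet test was set before its result was seen.

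The difference between the sexes was not the same in cluster 7 as in clusters 0 and 8 for 11 genes, by the interaction term of the edgeR model. The differences of the log2 fold changes were -1.45 for Tnfrsf4, -1.05 for Tnfsf8, -3.06 for Tmem108, -1.59 for Tcf7 and -2.26 for Tdrp. Chosen after their values were seen, other called genes were the transcription factor genes Trps1 (-1.11) and Zeb1 (-0.64), Chst2 (-1.77), the lysolipid receptor gene Gpr132 (-0.60) and the galectin gene Lgals1 (-0.61). Within cluster 7 alone, Lgals1 (log2 fold change -0.78, edgeR adjusted p = 0.000662) and Chst2 (-1.78, edgeR adjusted p = 0.0415) were called lower in males. That call of Chst2 was lost in 6 of 8 alternatives. Within the exhausted-like cells Lgals1 and Chst2 stood at -0.14 and -0.01 and were not called. The other genes named here were not called within cluster 7 alone. The real split gave 11 calls and the highest of the others gave 5, so that 1 of the 10 splits of the 6 libraries gave as many. These 10 splits are too few for a share under 0.05.

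Within these results, 7 genes with a higher level in cluster 7, Tnfsf8, Tmem108, Tcf7 and Tdrp among them, had a higher mean in males within clusters 0 and 8, where none of those tested passed over both clusters together. Free RNA from cells of cluster 7, whose share was larger in males, would give every gene the same ratio of excess to its level in cluster 7; the highest of these ratios, 12.4% for Gpr132, was 3.37-fold the lowest, but by 1.48 standard errors, so this explanation stays open. Doublets with cells of cluster 7 would have more UMIs, and without the fifth of cells with most UMIs in each library and cluster the median log2 fold change of the 5 genes past the low-count filter in both fits was 1.23, against 1.31 with all cells. The share of the change that was kept, 94.0%, speaks against doublets, but it ran from 39.9% to 101.2% when 1 library was left out, so they cannot be excluded either. A sex difference within the exhausted-like cells, the explanation that the design names, stays open. The tests of these genes within those cells cannot tell it apart from free RNA or doublets.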

How the results depend on the processing

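No paired analysis was possible because the number after the barcode could not be tied to the replicate numbers of the labels. For the same reason no replicate block was fitted. Sums without clusters 6 and 10, the same cluster mix and all interaction settings were chosen after seeing the data. Where a value below changed, the cause was not tested.

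Of the named genes over all CD8 T cells, 1854 values kept their direction and side of the threshold, 31 became called, 7 lost the call and 10 reversed, over all alternatives together. Within clusters 834 were kept and 290 lost the call, for lists 136 and 44, and for interaction genes 30 and 5. Reversed were Krt8 with limma-voom (0.081), Cd79b with the same cluster mix (-0.081) and 8 genes with 1 library left out, whose ranges were -1.22 to 0.75 for Krt8, -0.061 to 0.28 for Cd79b, -0.65 to 0.32 for Cd40lg, -7.61 to 1.01 for Hbb-bs, -0.25 to 0.033 for Ddx3x, -0.0091 to 0.20 for Hsp90aa1, -0.026 to 0.18 for Dnaja1 and -1.59 to 0.28 for Klra4. The sign turned without female library 6 for Ddx3x, Hsp90aa1, Dnaja1, Klra4 and Krt8, without female library 2 for Cd40lg and Hbb-bs and without male library 1 for Cd79b. None of these had passed the test.

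The count over all CD8 T cells was 136 with DESeq2, 127 of them outside the label-check lists. That count outside was 7 with no filter, 5 with thinned counts and 6 with the same cluster mix. With 1 library left out the counts ran from 9 to 16, and from 2 to 9 outside. Within clusters, the filter at 10 CPM gave 3 calls in cluster 0, 0 in 4, 1 in 5, 3 in 7 and 0 in 8, and DESeq2 gave 10 in cluster 0, 24 in 3, 4 in 4, 10 in 5, 3 in 8 and 2 in 10. A minimum of 50 cells removed no sum. With 1 library left out, the calls ran from 3 to 18 in cluster 0, 56 to 702 in 1, 7 to 42 in 2, 4 to 23 in 3, 1 to 13 in 4, 1 to 17 in 5, 4 to 15 in 6, 2 to 47 in 7, 1 to 5 in 8, 65 to 376 in 9, 0 to 10 in 10, and 163 to 1190 over all clusters.

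The share of cluster 7 lost its call with quasi-binomial regression (log2 ratio 1.34), with filtered cells (1.36) and with Leiden clusters (1.39), each with 0 shares called. With TMM over clusters 4 were called, cluster 7 and clusters 1 (0.55), 2 (1.16) and 9 (0.73). Cluster 10 reversed with TMM (0.072), with filtered cells (0.23) and without male library 3 (0.0093), and cluster 8 with Leiden clusters (0.20), which had no match for cluster 10. The Leiden cluster matched to cluster 8 held 397 of its 1695 cells, and 1233 lay in the one matched to cluster 0. For cluster 7 it held 1113 of 1752 cells, and 419 lay in the one matched to cluster 2. Over all cells, 74.8% lay in the Leiden cluster matched to their own. With 1 library left out, 0 to 2 shares were called, at log2 ratios of 0.90 to 1.38 for cluster 7, 0.70 to 1.38 for cluster 2 and -0.19 to 0.0093 for cluster 10.

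List calls were 1 with an estimated correlation and 3 with fry, and within clusters 12 with an estimated correlation. With 1 library left out they ran from 11 to 17 and from 97 to 127 within clusters, and the interaction calls from 4 to 47. Depth limits the smallest sums, with 199900 UMIs in cluster 10.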

Other observations

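Genes in the paragraphs on Ifitm and on the effector-like cluster were chosen after their values were seen. So were the comparison of counts between clusters in the leave-outs, the comparison of signs with cluster 7, the tests of the causes of the Gzma difference, the counts over other splits and the comparison of chromosomes.

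Ifitm1 had a negative log2 fold change in 11 of 11 clusters and was called lower in males in 5 of them, at log2 fold changes of -1.11 in cluster 0, -0.86 in cluster 3, -0.70 in cluster 5, -1.93 in cluster 9 and -1.12 in cluster 10. In cluster 9 Ifitm1 stood at 1150 ± 203 CPM in females and 300.4 ± 94.0 CPM in males (SD, n = 3 each, edgeR adjusted p = 0.000429). Ifitm2 was called in clusters 6 and 9 and Ifitm3 in cluster 9. The calls of Ifitm3 in cluster 9 (adjusted p up to 0.204) and of Ifitm1 in cluster 5 (up to 0.159) were lost in 4 of 9 alternatives each, that of Ifitm1 in cluster 0 in 3 of 9 (up to 0.106) and that of Ifitm2 in cluster 6 in 1 of 9 (up to 0.0504), while that of Ifitm2 in cluster 9 held in 9 of 9. The calls of Ifitm1 in clusters 3, 9 and 10, and those in the next paragraph, were not followed over the alternatives. Over all CD8 T cells Ifitm1 (adjusted p = 0.0852) and Ifitm2 (adjusted p = 0.170) did not pass.

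In the effector-like cluster 1, S100a4 stood at 1698 ± 184 CPM in females and 702 ± 69.9 CPM in males (SD, n = 3 each, log2 fold change -1.27, edgeR adjusted p = 1.95e-07), S100a6 at 2808 ± 124 and 1584 ± 120 CPM, and Lgals1 at 2137 ± 294 and 1158 ± 65.6 CPM. The chemokine receptor gene Ccr2 stood at 428 ± 10.8 and 250 ± 34.3 CPM. Bcl2, which encodes a protein that protects cells from apoptosis, was higher in males, at 274 ± 43.5 and 562 ± 89.2 CPM (log2 fold change 1.04), and was called in cluster 9 too (0.69).

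Clusters 1 and 9 held 343 and 268 of the 675 calls within clusters. A candidate explanation is that cells within these clusters lay nearer to cluster 7 in males and nearer to clusters 0 and 8 in females: 334 of 340 called genes in cluster 1 (98.2%) and 267 of 267 in cluster 9 had the sign of cluster 7 against clusters 0 and 8, against 73.3% and 72.9% of genes not called. The signs of genes not called are less certain, which lowers their share under any cause. Free RNA from cells of cluster 7, whose share was larger in males, would raise genes of cluster 7 in males. Of the genes with that sign, 140 of 334 in cluster 1 and 86 of 267 in cluster 9 were higher in males. The other 194 and 181 were higher in females, and such RNA would lower them in males by dilution alone. The size of such a dilution was not tested. The signs therefore cannot tell these explanations apart. Without female library 5 the counts of clusters 1 and 9 fell to 56 and 65, but the highest of the other clusters was then 15. In each of the other leave-outs too both clusters stood above every other cluster (195 and 310 against 47 without female library 2), which argues against 1 library as the whole cause. The depth of the sums is argued against too, since with every sum thinned to 199900 UMIs cluster 1 kept a count of 82 and cluster 9 of 44, with at most 3 in any other. Depth per cell was not tested and stays open, as do free RNA, the sex of the host and how the clusters were drawn. The median UMIs per cell in the libraries were 6488 to 6996 in females and 4319.5 to 6184 in males in cluster 1, and 7174 to 8444 and 4973.5 to 7245 in cluster 9.

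Gzma was lower in males over all CD8 T cells. Another mix of clusters in males is argued against as the whole cause. With the same mix in every library the log2 fold change was -1.16. Gzma was also lower in males in 11 of 11 clusters, at -2.53 to -0.59, with a call in 3. The call in cluster 0 was lost without male library 4 (adjusted p = 0.129) and without female library 6 (adjusted p = 0.0930). The -2.53 is that of cluster 7, which was not called (edgeR adjusted p = 0.801) and where the sexes overlapped. Female library 2 stood there at 39.2 CPM and male library 1 at 57.5 CPM, and the female SD of 326 CPM was larger than the female mean of 253 CPM. A single library is argued against too over all CD8 T cells, since the highest adjusted p over the leave-outs there was 0.0437. Free RNA is argued against as the whole cause if its share of the UMIs is no larger in the other clusters than in the lowest: with the level in the lowest cluster of each female library taken off, and nothing taken off the males, the females stood at 1510 ± 446 CPM against 732 ± 95.02 CPM (difference 777, 2.95 standard errors; lowest female library 997, highest male library 828). A part of the difference from free RNA stays open, as does the sex of the host, which is untested.

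With the 6 libraries divided 3 and 3 in 10 ways, the splits are too few for a share under 0.05. The real split called 11 genes over all CD8 T cells and the highest other called 1, and outside the label-check lists 3 against 1. Of these 3, Tsix overlaps Xist and Gm29650 lies on chromosome Y. Both can be called through the sex chromosomes alone, like the label-check genes. Gzma alone is left, no more than the 1 gene of another split. Within clusters the real split called 675 genes against 56, and it called 15 lists against 13 and 117 lists within clusters against 88. Tsix is among these genes, and the 2 label-check lists are among these lists. In each of these counts as they stand, 1 split gave as many, the real one. For shares the real split called 1 cluster and another called 2, so that 2 splits gave as many.

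On chromosome X, outside the label-check lists and Tsix, 251 genes with a mean of at least 5 CPM had a median log2 fold change of -0.02 and 58.6% were higher in females, against 52% of 8030 autosomal genes. With no limit on the level, 52.3% of 344 genes on chromosome X and 48.5% of 11430 autosomal genes were higher in females, and neither difference was tested.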
